A study of Homo sapiens with 2 samples.

How the data were processed

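The series holds 2 RNA-seq libraries of the human breast cancer cell line MDA-MB-231, 1 labelled as control and 1 labelled as treated with Carpesium cernuum extract (CCE). Per the labels' protocols, RNA was harvested with Trizol and libraries were made by standard Illumina protocols. The treatment text, 1 µg/mL for 24 h, stands on both samples, so groups were taken from the treatment characteristic of each sample, and what the control cells received is not given in the sources used here. HISAT2 and the genome builds hg19 and GRCh37 are named per the submitters' processing notes. The program that counted reads, its strand setting, the annotation release and the program behind the FPKM values are not given in the sources used here.

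The authors deposited a table of raw counts per Ensembl gene for each library, with 63677 gene IDs. Each table ends in 5 rows that name no gene and were left out of library sizes. They took 62.9% of the 15198936 records of the control library and 66.8% of the 105168383 records of the CCE library, most of them records aligned outside any counted gene (38.0% and 33.9%). Genes held 5633569 and 34884501 counts. The authors also deposited FPKM values, with 215170 rows per library and repeated gene IDs, so the rows were taken as transcripts and summed per gene. The depth behind the FPKM values is unknown. Among the 10102 protein-coding genes with a mean of at least 5 CPM, without 276 at 0 FPKM in both libraries, log2 ratios from counts and from FPKM correlated with Spearman's rho of 0.359 (pseudocount 1) and 0.342 (pseudocount 0.1), a correlation across genes, which are not independent replicates. Of all 10102 genes, 1194 were listed at 0 FPKM in the control and 351 in the CCE library. Counts were the main measure, as chosen before the data were examined, together with the gene lists, the named-gene rule and all alternatives not said below to be added later.

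Gene symbols, biotypes and coordinates came from GENCODE release 44 lifted to GRCh37, in which 55665 IDs were found; the 8012 others held 0.715% and 0.687% of counts. Libraries were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (0.987 for control, 1.01 for CCE). The log2 ratio of scaled counts, CCE over control, was taken with no pseudocount. Its exact 95% Clopper-Pearson interval came from the share of the gene's counts in the CCE library (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). PCR copies are not independent molecules, so intervals and floors cover counting error only. A gene at 0 in 1 library was given the bound from a floor of 3 counts, worth 0.540 CPM in the control and 0.0849 CPM in the CCE library. At equal expression, 10 control counts gave an interval of 0.514- to 2.20-fold, 100 gave 0.809- to 1.25-fold and 1000 gave 0.935- to 1.07-fold, so the shallower control library set the precision.

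A gene was measured at a mean of at least 1 CPM. It was called at least 2-fold higher or lower when its ratio passed 2-fold and its interval excluded 1. No test was run and no p-value is given, since each group has 1 library. For each of 42 gene lists (829 of 839 members matched), the median log2 ratio of measured members was given with its order-statistic 95% interval and its percentile among 10000 random protein-coding lists of the same size, matched on expression in 10 bins; percentiles under 2.5 or over 97.5 were said to stand apart. Percentiles are a description of these libraries. Lists with under 5 measured members got no median, a minimum set after the first results were seen, and the list of 5 members got the range of its members in place of an interval when alternatives were compared, also set then.

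Named genes were the 15 highest and 15 lowest protein-coding genes with a mean of at least 5 CPM and an interval excluding 1, up to 4 members of each list with the largest absolute log2 ratio, up to 2 of the most abundant members of lists that did not stand apart, and the 5 most abundant genes per library. Other genes are said to have been chosen after their values were seen. Some genes that meet this rule are not reported.

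The procedure was tested on simulated data: Poisson counts for CCE against control with the real means and depths over 14398 measured genes, of which 198 were altered. Intervals covered the true ratio in 95.4% of genes. At a 4-fold difference 100% of 66 genes, at 2.5-fold 97.0% of 67 and at 1.5-fold 1.54% of 65 were called at least 2-fold in the right direction. Of 14200 unaltered genes 71 were called at least 2-fold, and 1 at a mean of at least 5 CPM. The simulation held counting error only, with no spread between cultures and no GC trend. These rates therefore do not tell how many calls in the real libraries are false. Of 200 random lists, 4.50% fell outside percentiles 2.5 to 97.5.

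Alternatives chosen at the start were total-count, upper-quartile and DESeq2 1.42.0 scaling, the FPKM values on the log2(FPKM + 1) and log2(FPKM + 0.1) scales, no count filter or a mean of 5 CPM, thresholds of 1.5-fold and 4-fold, an interval beyond 2-fold, protein-coding genes only, a prior count of 5, summed counts per list, and matching on GC content as well. FPKM ratios were centred by subtracting the median over measured genes above 0 in both libraries (-0.21 and -0.25). Of the measured genes, 1583 were at 0 FPKM in both libraries and got no FPKM ratio, a choice made after the results were seen. Alternatives added after seeing the data were random thinning of the CCE counts to the control total, genes whose exons overlap no other gene on either strand, subtraction of the median log2 ratio of each of 10 GC classes, and the percentile of the inflammatory cytokine list with the CCE counts of all genes thinned.

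Without a stated strand setting, reads of a gene and of its partner on the opposite strand cannot be told apart, and 7996 of 14424 measured genes (55.4%) overlap another gene. Genes with near-identical copies are uncertain as well. Symbols not matched to the table were left out of their lists, SOD2 and UHRF1 among them. Sequencing batches could not be checked, since the labels give none.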

Results

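Gene expression was measured by RNA sequencing in MDA-MB-231, a human triple-negative breast cancer cell line. 1 library came from control cells and 1 from cells treated with an extract of the plant Carpesium cernuum (CCE) at 1 µg/mL for 24 h. The control library held 5633569 counts on genes and the CCE library 34884501, so each count was worth 0.180 CPM (library-scaled counts) in the control library and 0.0283 CPM in the CCE library. The comparison asks which transcripts differed between treated and control cells. With 1 library per group there was no replicate check: ratios are given with exact 95% Clopper-Pearson counting intervals, which cover counting error only and not the spread between cultures. Values below describe these 2 libraries.

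In the CCE library, genes of the oxidative stress response governed by the transcription factor NRF2 were higher. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, was 10.1-fold higher than in the control library (95% counting interval 8.95 to 11.4). Inflammatory cytokine genes were lower: the neutrophil-attracting chemokine gene CXCL1 was 20.8 times lower (log2 ratio -4.38, interval -4.61 to -4.15). Genes of mitosis, DNA replication, the extracellular matrix and the tubulin cytoskeleton were also lower. Of 14424 measured genes, 629 were at least 2-fold higher and 710 at least 2-fold lower with a counting interval that excluded 1. Among 11637 protein-coding genes these numbers were 379 and 504. Of the 629 and 710 genes, 205 and 139 were called on the same side by the authors' FPKM (pseudocount 1), and 90 in all on the other side. Measured genes at 0 FPKM in both libraries (1583 of 14424) could be called on neither side, and their number among the 629 and 710 is not given. Of the 39 gene lists with at least 5 measured members, 8 had a median above and 12 a median below that of random lists matched on expression, where the rule alone would place about 1.95 outside. That number holds for lists of genes drawn at random. These lists hold related genes and share some members, so it is not a chance level for a difference between 2 cultures.

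**Figure D1:**
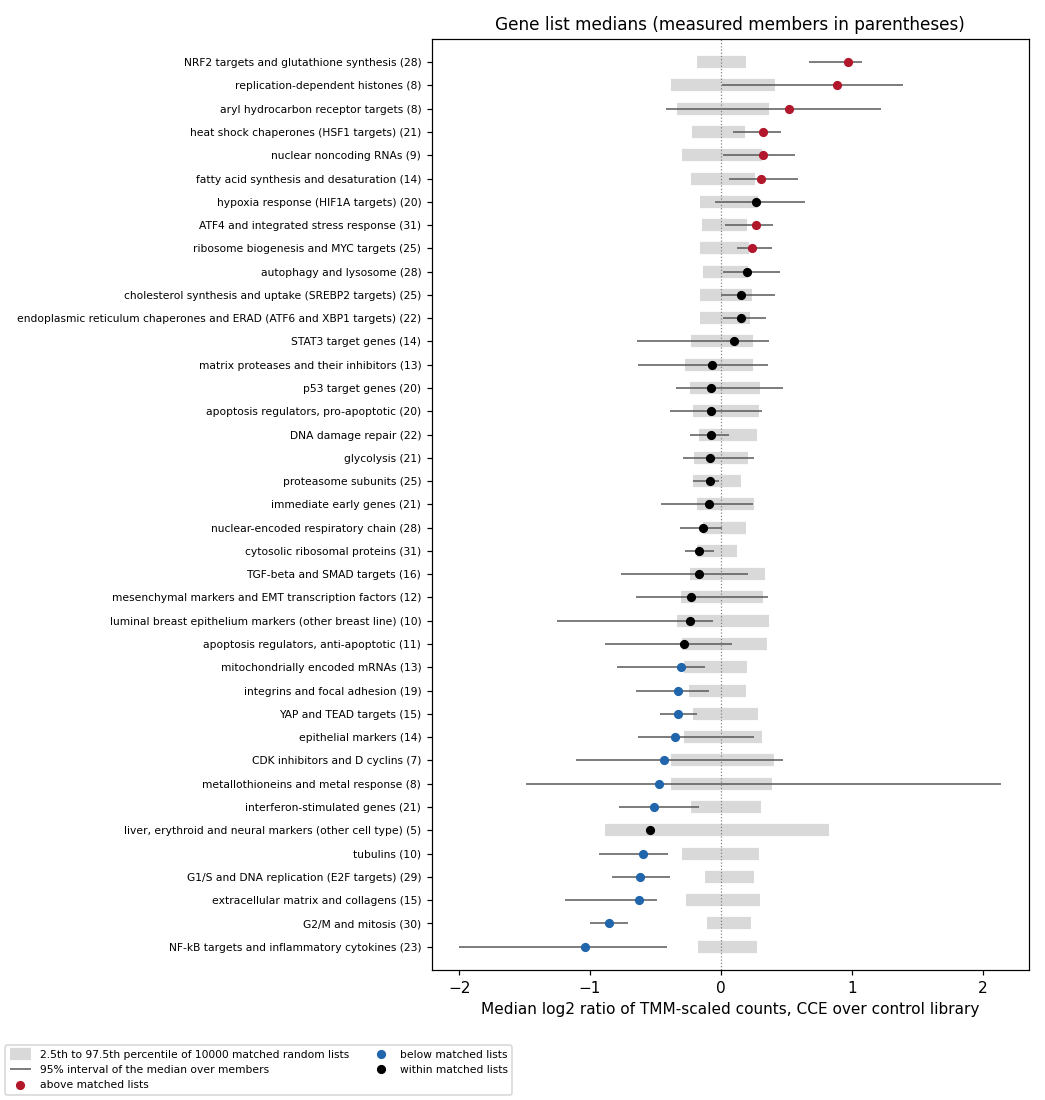
Median log2 ratio of each of 39 gene lists, CCE over control library, on the horizontal axis, with 1 list per line and its measured members in parentheses. Points are medians, thin lines their 95% interval over members (none for the list of 5 members), and grey bars the central 95% of medians of 10000 random lists matched on expression; the NRF2 list lies highest at 0.97 and the inflammatory cytokine list lowest at -1.04.

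All 28 members of the list of NRF2 targets and glutathione synthesis had a log2 ratio above 0, and 21 were at least 1.5-fold higher, 13 of them at least 2-fold. The list median was 0.97 (95% interval over members 0.68 to 1.08), above every one of the matched random lists (percentile 100). AKR1C1, an aldo-keto reductase that reduces steroids and reactive carbonyls, had 7 counts in the control library and 518 in the CCE library, 11.6-fold higher (interval 5.61 to 29.1). HMOX1, on chromosome 22 from 35776354 to 35790207 (GRCh37), had 281 and 17980 counts. AKR1B10, which reduces reactive aldehydes and retinal, was 7.60-fold higher (3.65 to 19.0) and AKR1C2 3.46-fold higher, at a log2 ratio of 1.79 (0.71 to 3.13). AKR1C1 and AKR1C2 are close paralogs, so how reads were divided between them is uncertain. Of 3 members chosen after their values were seen, the cystine transporter gene SLC7A11 had a log2 ratio of 1.61, and the genes of the glutamate-cysteine ligase subunits, GCLM and GCLC, had 1.03 and 1.04. The iron storage gene FTH1, among the 5 most abundant genes of the CCE library, was 1.71-fold higher (1.69 to 1.73); the gene on its opposite strand, BEST1, was listed with nearly as many counts.

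Inflammatory genes lay at the other end. In the list of NF-kB targets and inflammatory cytokines, 16 of 23 measured members were at least 1.5-fold lower, 12 at least 2-fold, and 0 were 1.5-fold higher. The median was -1.04 (-2.00 to -0.41), at percentile 0.00 of the matched lists. CSF3, which encodes the granulocyte growth factor G-CSF, had 30 counts in the control library and 5 in the 6.36-fold larger CCE library, a log2 ratio of -5.25 (-6.98 to -3.87). CXCL1, on chromosome 4 from 74735110 to 74737025, had 658 and 201 counts. CSF2, the gene of the myeloid growth factor GM-CSF, had a log2 ratio of -2.87 (-2.98 to -2.75), and IL1B, the gene of interleukin 1 beta, of -2.53 (-2.90 to -2.17). IL6 and CXCL8, named after their values were seen, had log2 ratios of -1.63 and -2.00. Interferon-stimulated genes were lower as well, with 8 of 21 measured members at least 1.5-fold lower and 2 at least 1.5-fold higher, and a median of -0.51 (-0.78 to -0.17, percentile 0.00). The antiviral genes OAS3 and IFIT3 had log2 ratios of -2.14 (-2.42 to -1.86) and -1.04 (-1.13 to -0.96); IFIT3 overlaps LIPA on the opposite strand.

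**Figure D2:**
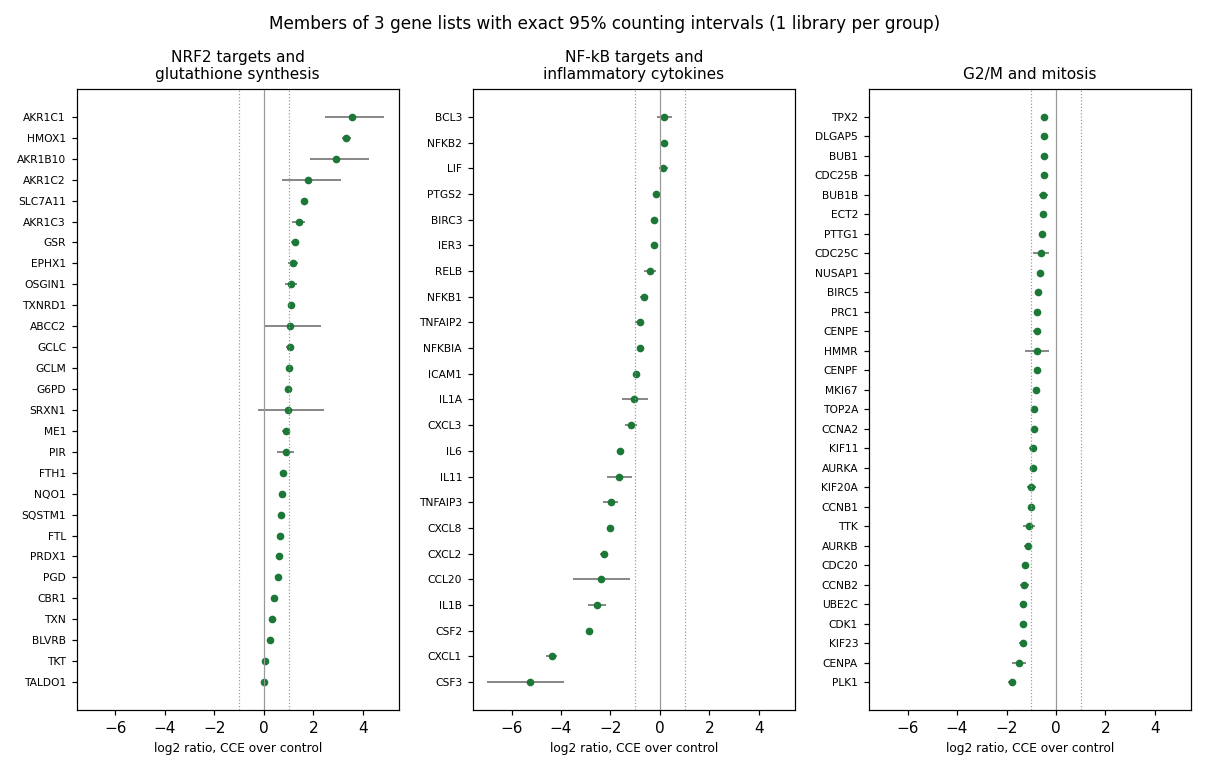
log2 ratio, CCE over control library, on the horizontal axis for each measured member of 3 gene lists, 1 gene per line, with the exact 95% counting interval as a bar. Dotted lines mark a 2-fold ratio either way; all 28 NRF2 members lie above 0, 20 of 23 inflammatory members lie below 0, and all 30 mitotic members lie below 0.

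Cell cycle genes were lower in the CCE library. All 30 members of the list of G2/M and mitosis had a log2 ratio below 0, 23 were at least 1.5-fold lower and 10 at least 2-fold lower, and the median was -0.86 (-1.003 to -0.713, percentile 0.00). The mitotic kinase genes PLK1 and CDK1 had log2 ratios of -1.79 (-1.96 to -1.63) and -1.33 (-1.44 to -1.22), the centromeric histone gene CENPA -1.49 (-1.77 to -1.19) and the cytokinesis kinesin gene KIF23 -1.35 (-1.50 to -1.20). Of 29 measured E2F targets of G1/S and DNA replication, 16 were at least 1.5-fold lower and 1 was higher, with a median of -0.62 (-0.84 to -0.39, percentile 0.00). E2F2 had -1.80 (-2.43 to -1.15) and TYMS, which encodes thymidylate synthase and overlaps ENOSF1 on the opposite strand, -1.44 (-1.55 to -1.33). The replication factor gene GINS1 had -1.10 (above 0 by FPKM at a pseudocount of 1) and ORC1, of the origin recognition complex, was 2.08-fold higher (log2 ratio 1.05, 0.67 to 1.46).

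The list of CDK inhibitors and D cyclins had a median of -0.44 over 7 measured members (-1.10 to 0.48, percentile 1.28), with CDKN2D at -1.10 (-1.33 to -0.88), CCND1, the gene of cyclin D1, at -0.71 (-0.76 to -0.65) and the CDK inhibitor gene CDKN1A at 0.48 (0.39 to 0.56). Matched on expression and GC content, that list lay at percentile 2.92 and no longer stood apart. Replication-dependent histone genes went the other way, with 5 of 8 measured members at least 1.5-fold higher, 0 lower, and a median of 0.89 (0.01 to 1.39, percentile 100), which was 0.38 with no count filter or over the members that overlap no other gene and 0.39 by summed counts. H4C8 had a log2 ratio of 1.39 (0.98 to 1.83) and the linker histone gene H1-2 of 1.16 (0.97 to 1.37). Many histone genes have near-identical copies within their class, so their counts are uncertain one by one.

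Genes of the matrix, adhesion and cytoskeleton were lower in the CCE library. In the list of extracellular matrix and collagens, 15 of 15 measured members had a log2 ratio below 0 and 9 were at least 1.5-fold lower, with a median of -0.63 (-1.19 to -0.49, percentile 0.00). The transmembrane collagen gene COL13A1 had -1.67 (-1.85 to -1.48), the matrix glycoprotein gene TNC -1.79 (-2.40 to -1.17), and the collagen genes COL1A1 and COL5A1 -1.57 (-2.53 to -0.54) and -1.19 (-1.44 to -0.94). By the authors' FPKM this median was -0.16, and TNC, COL1A1 and COL5A1 had ratios above 0. Of 10 measured tubulin genes, 6 were at least 1.5-fold lower (median -0.59, -0.93 to -0.40, percentile 0.01). The alpha-tubulin genes TUBA1A and TUBA1B had -1.13 (-1.25 to -1.01) and -0.93 (-0.96 to -0.89) and are close paralogs. The lists of integrins and focal adhesion (median -0.33, -0.65 to -0.09, percentile 0.26) and of YAP and TEAD targets (-0.33, -0.47 to -0.19, percentile 0.20) were lower with 5 of 19 and 3 of 15 members at least 1.5-fold lower. They included the laminin-binding integrin genes ITGB4 at -1.68 (-2.04 to -1.32, above 0 by FPKM at a pseudocount of 1) and ITGA6 at -1.21 (-1.29 to -1.13), and AXL, the gene of a receptor tyrosine kinase, at -0.95 (-1.0001 to -0.8898). Epithelial markers had a median of -0.35 (-0.63 to 0.25, percentile 0.91), with the tight junction genes CLDN3 at -1.32 (-2.29 to -0.27) and OCLN at 1.06 (0.44 to 1.74), the latter below 0 by FPKM.

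Among stress and lipid lists, the medians were smaller. Heat shock chaperones had a median of 0.32 (0.09 to 0.46, percentile 99.93), with 4 of 21 at least 1.5-fold higher and 1 lower. DNAJB4, a chaperone cofactor, was 2.04-fold higher (log2 ratio 1.03, 0.82 to 1.25), and CHORDC1, an HSP90 cochaperone, 1.70-fold. The cytosolic chaperone genes HSP90AA1 (0.71, 0.69 to 0.74) and HSPA4L (0.67, 0.46 to 0.89) were below 0 by FPKM. The list of ATF4 and the integrated stress response had a median of 0.27 (0.03 to 0.40, percentile 99.69), with 4 of 31 members at least 1.5-fold higher and 0 lower. That share of higher members was close to the share over all measured genes (1744 of 14424). SLC3A2, which encodes the heavy chain of amino acid transporters, and the asparagine synthetase gene ASNS were 2.20-fold and 2.08-fold higher (log2 ratios 1.14, 1.080 to 1.197, and 1.05, 0.93 to 1.17), and the stress cytokine gene GDF15 had 0.96 but was below 0 by FPKM. Fatty acid synthesis and desaturation had a median of 0.30 (0.06 to 0.59, percentile 98.85), with 3 of 14 members at least 1.5-fold higher. GPAM, of triglyceride synthesis, had 0.71 (0.40 to 1.05) and the elongase gene ELOVL6 0.59 (0.46 to 0.73). The malic enzyme gene ME1, shared with the NRF2 list, had 0.89 (0.72 to 1.06) but was below 0 by FPKM.

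Targets of the aryl hydrocarbon receptor had a median of 0.52 over 8 members (-0.42 to 1.22, percentile 99.79), with 3 at least 1.5-fold higher. CYP1A1, a cytochrome P450 of xenobiotic metabolism, was 2.33-fold higher (log2 ratio 1.22, 0.93 to 1.53), CYP1B1 had 0.79 (0.75 to 0.84) but lay below 0 by FPKM, and NQO1, shared with the NRF2 list, had 0.71. Ribosome biogenesis and MYC targets had a median of 0.24 (0.12 to 0.39, percentile 98.48), and 0.08 over the members that overlap no other gene. 3 of 25 members were at least 1.5-fold higher, a share close to that over all measured genes. They were PPAN (1.58, 0.50 to 2.92), POLR1B (0.77) and the nucleolin gene NCL (0.68), and all 3 were below 0 by FPKM. Nuclear noncoding RNAs had a median of 0.32 over 9 members (0.02 to 0.56, percentile 97.72), with MALAT1 at 1.23 (1.13 to 1.33) and NORAD at -0.62 (-0.68 to -0.55). Matched on expression and GC content this list lay at percentile 95.18, and by FPKM its median and MALAT1 were below 0. Metal response genes had a median of -0.47 over 8 members (-1.49 to 2.14, percentile 0.98) and went both ways: the metallothionein gene MT1G was 4.41-fold higher (2.83 to 7.28), while its paralogs MT1F, MT1E and MT1X had log2 ratios of -1.49 (-2.17 to -0.78), -0.97 (-1.07 to -0.87) and -0.88 (-1.02 to -0.73). The FPKM median of this list was above 0, as was MT1X.

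Mitochondrially encoded mRNAs had a median of -0.31 over 13 members (-0.80 to -0.12, percentile 1.47), and -1.36 by FPKM. MT-CO3 and MT-CO2, which encode cytochrome c oxidase subunits, had log2 ratios of -1.09 (-1.10 to -1.07) and -0.80 (-0.81 to -0.78), and MT-ATP6, of ATP synthase, -0.87 (-0.89 to -0.86). The mitochondrial genome held 10.5% of counts in the control and 8.20% in the CCE library. The 5 most abundant genes were MT-CO2, MT-ND4, MT-ND2, MT-ATP6 and MT-RNR2 in the control library, and MT-ND2, MT-ND4, MT-RNR2, FTH1 and MT-CO2 in the CCE library. MT-CO2 was listed at 0 FPKM in the control library despite 86623 counts.

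The largest ratios of named protein-coding genes included genes outside the lists. Highest of those with a mean of at least 5 CPM was F2RL2, which encodes a protease-activated receptor, with 13 and 1002 counts, 12.1-fold higher (7.06 to 22.9). WIPF3 (6.25-fold, 3.46 to 12.6), NIPAL2 (4.25-fold, 3.04 to 6.14), the zinc finger genes ZNF14 (3.82-fold) and ZNF41 (3.66-fold), and GEMIN8 (3.59-fold), of small nuclear ribonucleoprotein assembly, were also among the 15 highest. TMBIM4 (11.6-fold) and BLOC1S1 (4.97-fold) share exons with a read-through gene on the same strand, BOLA2B (6.38-fold) and DHFR2 (4.15-fold) have near-identical copies, and TMBIM4 and HKDC1 (5.39-fold) were lower by FPKM, so these 5 are uncertain. Of the 15 highest, 13 had under 50 control counts, 8 were listed at 0 FPKM in the control library, and 12 were higher by FPKM, with WIPF3 at 0 FPKM in both libraries.

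All of the 15 lowest were lower by FPKM as well. Beside CXCL1, CSF2, IL1B, OAS3 and the chemokine gene CXCL2 (log2 ratio -2.26, -2.42 to -2.11), they held HAS2, a hyaluronan synthase (-3.00, -3.52 to -2.48), the organic anion transporter gene SLCO4A1 (-2.88, -3.37 to -2.40), the lymphoid transcription factor gene POU2F2 (-2.79, -2.95 to -2.62) and the potassium channel gene KCNN3 (-2.61, -3.21 to -2.01). The others were ASB2 (-2.20), the pattern recognition gene PTX3 (-2.10, -2.31 to -1.89), DISP2 (-2.10), C16orf74 (-2.10), CAVIN2, of caveolae (-2.08), and the epithelial transcription factor gene SPDEF (-2.07, -2.35 to -1.79).

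Lists on cell death did not stand apart from matched lists. The p53 targets had a median of -0.07 (-0.35 to 0.48, percentile 20.6), with 3 of 20 members at least 1.5-fold higher and 4 lower: SESN1, of the stress-induced sestrins, had a log2 ratio of 1.34 (0.53 to 2.27), and the DNA damage sensor gene DDB2 -1.35 (-1.68 to -1.02). Pro-apoptotic regulators had -0.08 (percentile 16.5), with the initiator caspase gene CASP9 at 1.01 (0.42 to 1.65) and BBC3, which encodes PUMA, at -0.80 (-1.24 to -0.34). Anti-apoptotic regulators had -0.28 (percentile 3.08, and 2.13 when matched on expression and GC), with BCL2L2 at -1.02 (-1.26 to -0.77), the decoy receptor gene TNFRSF10D at 0.97 (0.76 to 1.18) and MCL1 at 0.01 (-0.08 to 0.09); their FPKM median was above 0. DNA damage repair genes had -0.08 (percentile 9.94), with PARP1 at -0.23.

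Most metabolic and protein quality lists also lay within the matched range. Endoplasmic reticulum chaperones had a median of 0.15 (percentile 89.8), with DNAJB9 at 0.69 (0.45 to 0.93), and cholesterol synthesis and uptake 0.16 (percentile 87.9, below 0 by FPKM). Glycolysis had -0.08 (percentile 18.1), with PKM at 0.41 and GAPDH at -0.29, proteasome subunits -0.09 (percentile 22.9), with PSMD2 at -0.27, and cytosolic ribosomal proteins -0.17 (percentile 4.17, and 0.68 matched on GC as well), with RPLP0 at -0.27. The nuclear-encoded respiratory chain had -0.14 (percentile 2.57, and 1.27 matched on GC as well), with ATP5F1B at -0.25. Hypoxia targets had 0.27 (percentile 96.7), with the lipase inhibitor gene ANGPTL4 2.31-fold higher (2.005 to 2.684) and the hormone gene STC1 at -1.12 (-1.48 to -0.76). Autophagy and lysosome genes had 0.20 (percentile 96.97). Of these, the autophagy receptor gene SQSTM1, shared with the NRF2 list, had a log2 ratio of 0.68 (0.65 to 0.70). The lysosomal galactosidase gene GLA, which lies opposite RPL36A, had 1.18 (1.01 to 1.35).

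Signalling and lineage lists gave medians of -0.09 for immediate early genes (percentile 11.3), with EGR1 at 1.24 (0.88 to 1.62) and KLF6 at -0.70, -0.17 for TGF-beta and SMAD targets (percentile 6.33), 0.10 for STAT3 targets (percentile 76.7, below 0 by FPKM), with SOCS3 at -0.64, and -0.07 for matrix proteases and their inhibitors (percentile 29.0), with the urokinase gene PLAU at -1.07 (-1.14 to -0.99). Mesenchymal markers had -0.23 (percentile 6.56), with the intermediate filament gene VIM at -1.05 (-1.08 to -1.03) and the fibronectin gene FN1 at -0.97 (-1.05 to -0.88); the list was at -0.81 by summed counts, which VIM dominates, but at 0.36 over the members that overlap no other gene and above 0 by FPKM. Luminal breast markers had -0.24 (percentile 6.80), with KRT18 at -0.28. Markers of liver, erythroid and neural cells had -0.54 over 5 members (percentile 11.1), with GFAP at -2.16 (-2.92 to -1.38); by FPKM both were above 0, and the list was at 0.20 over members with a mean of at least 5 CPM. Of the lists for other cell types, 1 leukocyte marker (CD74, -0.24), 2 endothelial markers (KDR, -0.70, and ESAM, -0.55) and 1 fibroblast or adipocyte marker (COL1A1) were measured, too few for a median.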

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

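Outside the gene counts, the rows of the count tables that name no gene held 2 shares above the level of the control library. Records aligned to more than 1 place made up 17.3% of the CCE library (exact 95% counting interval 17.28 to 17.29) and 11.6% of the control library (11.58 to 11.61). Records that were not aligned made up 10.95% of the CCE library and 7.67% of the control library. These shares entered no comparison of genes, and no explanation of either was tested.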

How the results depend on the processing

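The thinned, overlap-free and GC-adjusted alternatives were chosen only after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. Against 629 genes at least 2-fold higher and 710 lower, other scalings gave 701 and 652 (total counts), 615 and 718 (DESeq2) and 527 and 781 (upper quartile), and their shift of all log2 ratios stayed under 0.1. Counts beyond 1.5 times apart came, by construction of the setting, from a mean of 5 CPM (288 higher, 331 lower), thresholds of 1.5-fold (1744, 1628) and 4-fold (116, 85), an interval beyond 2-fold (104, 217), protein-coding genes only (379 higher) and overlap-free genes (294, 326). Thinning gave 566 and 673, with 459 and 517 of the original genes among them, and the GC adjustment 517 and 739.

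The authors' FPKM values gave a different picture, and the cause was not tested. They put 2532 genes higher and 1542 lower with a pseudocount of 1 (62.2% of calls higher, against 47.0% by counts) and 3529 and 2061 with 0.1 (63.1%), with no counting interval to limit calls. Of the genes called by counts, 205 and 139 were called on the same side with a pseudocount of 1, and 90 on the other side. With a pseudocount of 0.1 these numbers were 281 and 217, and 163. Genes at 0 FPKM in both libraries had no FPKM ratio and could be called on neither side. With pseudocounts of 1 and 0.1, list medians moved to -0.16 and -0.13 for extracellular matrix, -1.36 and -1.32 for mitochondrial mRNAs, 0.28 and 0.33 for anti-apoptotic genes, -0.22 and -0.19 for cholesterol synthesis and -0.35 and -0.30 for the proteasome. They turned to 0.23 and 0.28 for metallothioneins and to -1.11 and -1.16 for nuclear noncoding RNAs.

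Settings were compared for 181 named genes, which leave out list members named only for their abundance and the genes chosen after their values were seen. Of the 177 with an FPKM ratio, 34 lay on the other side of 0 by FPKM with at least 1 of the pseudocounts, among them 25 of the 140 that were at least 1.5-fold apart by counts with an interval excluding 1. Those 25 follow. Turned from higher to lower, with pseudocounts of 1 and 0.1, were TMBIM4 (-3.24, -4.10), HKDC1 (-0.65, -2.28), HSP90AA1 (-4.11, -4.12), HSPA4L (-0.21, -0.34), GDF15 (-1.07, -1.08), HSD17B7 (-0.46, -0.47), ME1 (-0.19, -0.17), NCL (-4.26, -4.37), POLR1B (-2.34, -3.91), PPAN (-1.18, -1.23), PSMA2 (-2.12, -2.10), OCLN (-0.20, -0.23), CYP1B1 (-4.14, -4.37) and MALAT1 (-3.78, -3.90). Turned from lower to higher were MT-CO2 (9.20, 12.56), XRCC2 (1.90, 4.80), COL1A1 (0.32, 0.61), COL5A1 (1.35, 2.81), TNC (0.31, 1.07), MT1X (0.49, 0.54), AGR2 (1.16, 1.95), SERPINA1 (1.38, 3.75), GFAP (0.63, 2.38) and, with a pseudocount of 1 alone, GINS1 (0.0914) and ITGB4 (0.0878), both of them only through the centring.

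None of the 181 genes (180 under upper-quartile scaling) changed side under the other scalings, the prior count of 5, thinning or the GC adjustment. Nor did any of the 20 lists that stood apart, whose medians stayed within their interval under those settings, both filters and summed counts. Staying on the same side under the scalings, prior count, thinning and GC adjustment decides little, since it was nearly fixed in advance. Most of these genes were picked for large ratios, and the lists for medians beyond those of random lists. The scalings shift all ratios slightly, the prior count shrinks them and thinning leaves them unchanged on average. The median log2 ratio subtracted was only 0.16 in the lowest GC class and -0.19 in the highest. Over overlap-free members ribosome biogenesis was at 0.081, and 1 of the 20 lists, tubulins, had no such member. Those intervals are wide for some lists: histones dropped from 0.89 to 0.38 with no count filter or without overlapping members and to 0.39 by summed counts, and metallothioneins were at -0.18 at a mean of 5 CPM. By FPKM epithelial markers were at -0.11 and -0.07, and interferon-stimulated genes at -0.25 with a pseudocount of 1.

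Among lists that did not stand apart, DNA repair moved to -0.24 with the GC adjustment and mesenchymal markers to -0.81 by summed counts. In 8 of these lists the median changed sign under some setting. Without overlapping members it was 0.36 for mesenchymal markers, -0.46 for STAT3 targets, 0.12 for matrix proteases and 0.20 for liver, erythroid and neural markers (also at a mean of 5 CPM). By FPKM (pseudocounts of 1 and 0.1) these 4 were at 0.21 and 0.26, -0.37 and -0.33, 0.02 and 0.06, and 0.40 and 1.53, and p53 targets at 0.13 and 0.17; TGF-beta targets, anti-apoptotic genes and cholesterol synthesis changed sign by FPKM too. Matched on GC as well, CDK inhibitors (percentile 2.92) and nuclear noncoding RNAs (95.18) no longer stood apart, while anti-apoptotic genes (2.13), the respiratory chain (1.27) and ribosomal proteins (0.68) did. The control depth limits what could be seen: at 10 control counts a ratio of 2.20-fold is within counting error.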

Other observations

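The families below, the antisense genes, the pseudogenes and the FPKM ratios of overlapping genes were examined, and their tests chosen, only after the data were seen, as were the tests by thinning, GC adjustment and overlap-free members and the reading of these tests together with percentiles. Among 130 groups of at least 10 measured protein-coding genes that share the start of their symbol, 14 had a median above and 12 a median below random lists matched on expression and GC content. The rule alone would give 6.50 if the genes of each group were drawn at random. Zinc finger genes of the ZNF family, most of them DNA-binding transcriptional regulators, were higher in the CCE library: 141 of 415 were at least 1.5-fold higher and 16 lower, with a median log2 ratio of 0.39 (95% interval over members 0.33 to 0.46, percentile 100). The related ZSCAN genes had a median of 0.73 over 15 members (0.30 to 1.00, percentile 99.97), with 8 at least 1.5-fold higher and 0 lower. The medians of both families were above 0 by FPKM as well (0.80 and 2.26, pseudocount 0.1) and after the GC adjustment (0.32 and 0.67). An FPKM median above 0 says little by itself, since some families lower by counts had one too. KIF had -0.21 by counts and 1.19 by FPKM, and ARHGAP -0.35 and 0.62, while COL stayed below 0 (-0.67 and -0.27). RNA helicases of the DDX family had a median of 0.35, with 7 of 31 at least 1.5-fold higher and 2 lower. RNA-binding RBM genes had 0.33, with 5 of 31 at least 1.5-fold higher and 3 lower. Their medians were 0.36 and 0.47 by FPKM, and smaller after the GC adjustment (0.16 and 0.21). Annexins (ANXA, calcium-dependent membrane binding) had a median of -0.43 whose interval over members included 0 (-1.40 to 0.13), and -0.86 by FPKM. Keratins (KRT) had a median of -0.53 and tetraspanins (TSPAN) of -0.38, with -0.14 and 0.03 by FPKM. Semaphorins (SEMA) had -0.65 (interval -1.32 to 0.31) but 0.89 by FPKM.

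Inflammatory cytokine genes were lower in the CCE library, with a list median of -1.04. Reads of overlapping genes do not account for it: over the 15 members that overlap no other gene the median was -1.65, with an interval over members of -2.53 to -0.64. Both lay below the bound of -0.5, which was written before this test was run but after the data had been seen. A GC trend between the libraries does not account for the whole of it either, since the median was -1.23 after the GC adjustment (-2.17 to -0.40) and lay at percentile 0.00 of lists matched on expression and GC content. With the CCE counts thinned to the control total, the median was -0.95 (-2.03 to -0.28), at percentile 0.00 of matched lists thinned in the same way. Thinning leaves each ratio unchanged on average, so this result decides nothing about the deeper CCE library. In the GC and thinning comparisons the interval over members reached above the bound, so the reading on GC rests on its percentile. A difference between cultures that has nothing to do with the extract may account for the pattern and cannot be told apart from an effect of the extract, because each group has 1 library.

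Some genes that share exons with another gene on the same strand, such as TMBIM4, stood among the highest by counts. They were 3 of the 15 highest, a share similar to that over all measured protein-coding genes (2073 of 11637). If reads set aside as ambiguous differed between the libraries, such genes should be called higher more often. Of 2073 protein-coding genes with such an overlap 4.05% were at least 2-fold higher, against 3.08% of the 9564 others. The ratio of 1.31 lies between the bounds set for and against this explanation and leaves it open. Overlapping genes were also called at least 2-fold lower slightly more often (4.63%, against 4.27%). Ambiguous records made up 1.59% of the control and 1.36% of the CCE library, and records on genes 37.1% and 33.2%. These shares cover all genes and not the overlapping ones alone. A real difference stays open too: the median FPKM log2 ratio of the 84 overlapping genes called higher lay 0.88 above that of all genes without such an overlap, but these genes were picked for being higher, so the test decides nothing. Other genes called higher had a larger FPKM median (1.42, against 1.03), and over all overlapping genes it was 0.08, against 0.15 for the others.

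Many genes lying opposite another gene carried its counts in both libraries. BEST1, a gene of the retinal pigment epithelium named after its values were seen (chromosome 11, 61717535 to 61732987 on GRCh37), had 30162 counts in the control and 314703 in the CCE library, and FTH1 opposite it 30842 and 334678. Over 333 noncoding genes with at least 80% of their exons opposite a protein-coding gene of at least 100 counts, the median count per base was 1.25 times that of the protein-coding gene in the control and 1.18 times in the CCE library, with a wide spread between genes (quartiles 0.101 and 3.08 in the control). This suggests, as a hypothesis, that reads without strand information were counted by strand, so that such antisense genes hold reads of the gene opposite; records outside any counted gene were also 1.03 and 1.02 times the counts on genes. No biological explanation was tested.

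Processed pseudogenes, which are intronless copies of other genes, were often higher in the CCE library: of 491 measured, 84 were at least 2-fold higher and 13 lower, with a median log2 ratio of 0.27 (0.16 to 0.38, percentile 100 among protein-coding lists matched on expression). For protein-coding genes the median was 0.05. The random lists were not matched on GC content here. Since these pseudogenes are copies of other genes, their counts are uncertain, and no explanation of the pattern was tested.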
